A study of Mus musculus with 14 samples.

How the data were processed

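Kidney RNA from 14 mice was measured by RNA sequencing. The labels give 4 groups: WT untreated (n = 3), cKO untreated (n = 3), WT cisplatin (n = 4) and cKO cisplatin (n = 4), where cKO stands for conditional knockout of Ripk4. The cisplatin mice had received 15 mg per kg into the abdomen and kidneys were taken 4 days later. Total RNA was extracted with Trizol and made into Illumina TruSeq libraries. Replicate numbers follow the order of the sample records, each library was taken as 1 animal, and the labels give no pairing, batch, sex, age or Cre line.

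Reads were aligned with HISAT2 2.0.5 to mm10, per the submitters' processing notes, and the read counter, the annotation release and the strand setting are not stated there. The table holds 1 value per gene and library in FPKM, computed by the authors as reads per gene divided by the gene's length in kilobases and by the reads assigned to genes in units of 1 M. It lists 49584 genes, 1 further line was emptied for this work and not used here, and 0 of its columns lacked a sample. Of the gene IDs, 99.5% were found in GENCODE M21, and 91.5% had the same coordinates there. Coordinates are those of the table, and 95 symbols belonged to more than 1 gene ID, so genes were joined by ID.

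The depth was read from the FPKM steps. Each library's values, multiplied by gene length, were whole multiples of 1 step, which gave 36.7 to 77.0 M assigned reads per library. Whole reads were recovered in this way for 29479 of the 29480 genes with a value above 0. The M21 length gave them for 11582 genes (tolerance 0.0001 reads per read), and a length found by searching up to 40000 bases for 17897 (tolerance 1e-05). With 1 read in a gene of 1 kb, FPKM ranged from 0.0130 to 0.0273 over the libraries. These floors cover counting error only, since reads carry no molecular identifiers. No 2 libraries were identical (0 pairs).

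FPKM values were used as deposited, with no further scaling, and transformed as log2(FPKM + 1). Genes with a mean of at least 0.5 FPKM over the 14 libraries were kept, which left 15193 genes and removed 34391. The added 1 makes log2 fold changes of genes near or below 1 FPKM smaller than their ratios. A fold printed for a gene of a few FPKM is therefore understated.

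All 4 groups entered a single limma 3.58.1 model in R 4.3.3 with a mean per group and a moderated spread with a mean-variance trend. The 5 comparisons were cisplatin against untreated in each genotype, cKO against WT in each treatment, and the difference of the cisplatin responses, cKO minus WT. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes kept, and a gene was called at an adjusted p under 0.05. "Rose" and "fell" refer to called genes, and errors of log2 fold changes are standard errors from this model.

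Before the data were examined, the groups, the comparisons, the lists, the rule for naming genes and most alternatives were fixed. The 36 gene lists covered tubular injury, p53 targets, proximal tubule transport, proximal tubule metabolism, acyl-CoA synthetases (set under the name medium-chain, but holding Acss and Acsf genes beside the Acsm family), fatty acid oxidation, the tricarboxylic acid cycle with the respiratory chain, ferroptosis suppressors, ferroptosis promoters and markers, NRF2 targets, antioxidant enzymes, necroptosis and pyroptosis, inflammatory cytokines and NF-kB targets, interferon-stimulated genes, extracellular matrix and fibrosis, cell cycle, endoplasmic reticulum stress with the integrated stress response, Wnt and epithelial differentiation, RIP kinases and immediate-early genes. They also covered markers of macrophages, neutrophils, lymphocytes, endothelium, podocytes, thick ascending limb with distal tubule, collecting duct and fibroblasts, and genes of red blood cells, adipose tissue, adrenal gland, skeletal muscle, mitochondrial DNA, male-biased and female-biased kidney expression and sex chromosomes. Lists were tested against the other genes with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Lists needed at least 5 kept members, which 32 of the 36 had. Camera with an estimated correlation and fry were run beside it. Lists share members: Gclc, Gclm, Txnrd1, Slc7a11 and Gsr are both ferroptosis suppressors and NRF2 targets. Slc22a30, Slc7a13, Cyp2e1 and Acsm3 are male-biased genes that proximal tubule or acyl-CoA synthetase lists also hold. Results of such lists are not independent.

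Genes were named by rule: Ripk4 and Acsm1, the 10 largest rises and 10 largest falls of each comparison, and up to 4 members with the smallest p of each list reported. The largest changes were taken among called genes with a mean of at least 1 FPKM, without predicted gene models and, except for the difference of responses, without overlap between the groups' libraries. Groups of single values were compared by exact permutation of library labels, two-sided. The smallest p is 0.0286 for 4 against 4 libraries (70 arrangements) and for 3 against 4 (35 arrangements), and 0.10 for 3 against 3 (20 arrangements). Differences of responses were tested over 1400 exchanges of genotype within treatment. The size of the response was the mean over genes called for the mean effect of cisplatin, each signed by that mean effect. The share of the WT response takes a library's difference from the mean of the untreated libraries of its genotype (itself left out) over the genes called in WT. That difference was projected on the WT log2 fold changes. The shares of the 4 WT cisplatin libraries therefore average 1 by construction, and taking the genes from WT favours WT over cKO.

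Alternatives were other pseudocounts (0.1 and 5), other filters (none, or a mean of 5 FPKM), median-of-ratios, total and quantile scaling, array weights, no trend, a robust fit, thresholds of adjusted p under 0.1 or a 2-fold change, only the groups compared, leaving out each library, and leaving out the 3 libraries whose titles carry a higher number series (WT cisplatin replicate 2 and cKO cisplatin replicates 2 and 3). Some were chosen after seeing the data: limma voom on the recovered reads, leaving out 2 cKO cisplatin libraries together, leaving out the 3 libraries with the highest FPKM totals, and the FPKM total as a covariate. Sex was not used as a covariate, since the sex chromosome genes showed no difference in sex between libraries. DESeq2, planned only for a table of counts, was not run.

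The test was checked on simulated reads for 14791 to 14810 genes, about 100 of them changed by 2-fold and about 100 by 4-fold. The simulated spread between libraries was that of the 3 groups other than cKO cisplatin. The cKO cisplatin libraries varied more and share the pooled spread of the real fit, so the shares recovered may overstate what the real data allowed. The test recovered 64.6% of 2-fold and 92.0% of 4-fold changes for cisplatin in WT, 71.0% and 92.9% for cisplatin in cKO, and 64.6% and 90.0% for genotype without drug. For genotype after cisplatin it recovered 68.0% and 96.0%, and for the difference of responses 53.0% and 81.0%. False calls numbered 8, 17, 6, 12 and 6 in that order (4.88%, 9.44%, 3.75%, 6.86% and 4.29% of the calls). The list that was changed was called in each comparison, with 0 of 19 unchanged lists. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.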

Results

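Kidneys of WT mice and of mice with a conditional knockout of Ripk4 (cKO) were profiled by RNA sequencing, without drug and 4 days after 15 mg per kg of cisplatin. Ripk4 encodes a receptor-interacting serine/threonine kinase known for its part in epidermal differentiation. Cisplatin is a platinum drug that crosslinks DNA and injures the proximal tubule. The series title also names oxidative stress, ferroptosis (cell death by lipid peroxidation) and ACSM1, a mitochondrial medium-chain acyl-CoA synthetase. Untreated groups held 3 libraries each and cisplatin groups 4 each. Assigned reads were 64.9, 43.7 and 77.0 M in the WT untreated libraries and 41.4, 41.7 and 38.2 M in the cKO untreated ones. They were 44.0, 40.9, 54.3 and 51.7 M in WT cisplatin and 36.7, 50.5, 47.4 and 41.7 M in cKO cisplatin. Xist stayed at or under 0.0348 FPKM and the Y-linked Ddx3y at or above 14.2 FPKM in the 14 libraries. Gene levels below are mean FPKM ± SD, and fold changes are log2 ± SE on log2(FPKM + 1).

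Ripk4 (ENSMUSG00000005251, mm10 chromosome 16, 97741933 to 97763737) had lower means in the cKO groups and was not absent there. Its FPKM was 7.18, 8.11 and 8.51 in the WT untreated libraries and 3.68, 3.98 and 4.61 in the cKO untreated ones. The means were 7.93 ± 0.682 (SD, n = 3) against 4.09 ± 0.472 (SD, n = 3). After cisplatin it was 7.61, 10.6, 13.3 and 9.0 in WT and 5.32, 5.62, 9.09 and 3.61 in cKO. The means were 10.1 ± 2.46 (SD, n = 4) against 5.91 ± 2.30 (SD, n = 4). The table gives 1 value per gene, so a deleted exon could not be looked at, and the labels do not say which cells carry the deletion. The untreated difference was −0.81 ± 0.24 (limma adjusted p = 1.00, exact permutation p = 0.10, two-sided, the smallest that 3 against 3 libraries can give). After cisplatin it was −0.72 ± 0.21 (adjusted p = 0.0216, exact permutation p = 0.0857). That call was lost without the library labelled WT cisplatin replicate 3 (−0.59, adjusted p = 0.0723) or cKO cisplatin replicate 4 (−0.55, adjusted p = 0.0658). Over all alternatives its adjusted p ranged from 0.00494 (without cKO cisplatin replicate 3) to 0.0965 (array weights, −0.45), and it was 0.0806 with only the groups compared. Cisplatin itself was not called for Ripk4, with 0.30 ± 0.23 in WT and 0.39 ± 0.23 in cKO (adjusted p = 0.336 and 0.549).

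Acsm1 (ENSMUSG00000033533, mm10 chromosome 7, 119607026 to 119662515) fell with cisplatin in WT from 137 ± 16.1 (SD, n = 3) to 30.6 ± 3.19 (SD, n = 4), a log2 fold change of −2.13 ± 0.31 (adjusted p = 2.41e-04). All 4 treated libraries lay below all 3 untreated ones. In cKO its level was 144 ± 18.8 (SD, n = 3) untreated and 93.2 ± 61.9 (SD, n = 4) after cisplatin. The single values after cisplatin were 66.9, 49.9 and 71.1 in 3 libraries and 185 in the library labelled cKO cisplatin replicate 4. That difference was not called (−0.81 ± 0.31, adjusted p = 0.325), and without this library Acsm1 fell by 1.20 ± 0.15 to 62.6 ± 11.2 (SD, n = 3, adjusted p = 0.00130). After cisplatin Acsm1 was higher in cKO than in WT by 1.39 ± 0.29 (adjusted p = 0.00415, exact permutation p = 0.0286). Each cKO library lay above each WT library. Without replicate 4 the difference was 1.00 (adjusted p = 0.00105). The difference of the 2 responses was 1.32 ± 0.44 and was not called (adjusted p = 0.109), and without replicate 4 it was 0.93 and passed (adjusted p = 0.0393). Acsm1 overlaps the kept genes Gm19950 and RP23-306P12.3, and the counting strand is not stated. Reads shared with other Acsm genes are a further limit.

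**Figure D1:**
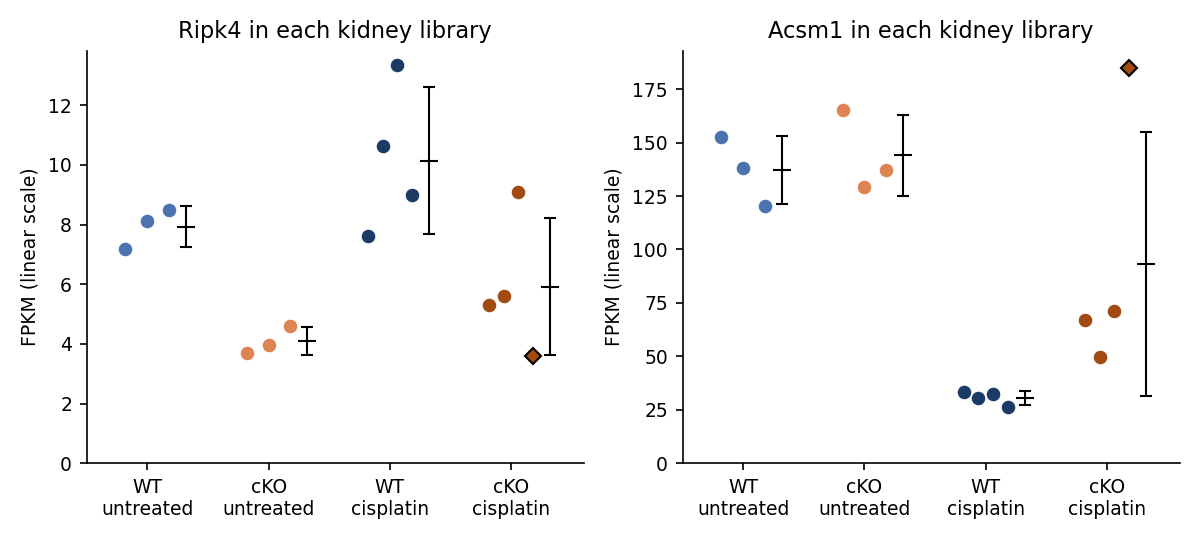
FPKM of Ripk4 (left) and Acsm1 (right) in each of the 14 kidney libraries on linear axes, with the mean and SD of each group in black and the library labelled cKO cisplatin replicate 4 as a black-edged diamond. Ripk4 lay between 3.68 and 4.61 in the cKO untreated libraries and between 7.18 and 8.51 in the WT untreated ones, and Acsm1 lay between 26.1 and 33.4 in the WT cisplatin libraries.

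The comparison of cisplatin with no drug in WT asks what the drug did to the kidney. Genes of tubular injury rose most. Lcn2 (neutrophil gelatinase-associated lipocalin) rose from 2.52 ± 1.000 (SD, n = 3) to 388 ± 101 (SD, n = 4), 6.79 ± 0.86 (adjusted p = 9.05e-05). Havcr1, which encodes kidney injury molecule 1, rose from 5.91 to 739.6 ± 403 (6.57 ± 0.70), and the keratin Krt20 from 0.218 to 101 ± 39.7 (6.31 ± 0.50). The other largest rises were Cdkn1a, which encodes the p21 inhibitor of the cell cycle (4.63 ± 1.39 to 357 ± 99.1), complement C3 (5.78 ± 0.56) and Cyp4a14 (5.35 ± 1.04). They were followed by the fibrinogen chain Fgg (5.08 ± 0.54), osteopontin (Spp1, 344 to 9894 ± 2472), the carboxylesterase Ces2e (4.71) and the cytokine Gdf15 (4.70). The largest falls were the globins Hbb-bs (458 ± 86.0 to 0.0779 ± 0.101, −8.72 ± 1.57) and Hba-a1 (249 ± 45.7 to 0.144 ± 0.237) and the methyltransferase Inmt (1009.8 ± 68.6 to 16.4 ± 11, −6.04 ± 0.54). The globins Hba-a2 and Hbb-bt, at 39.0 and 38.1 without drug, were listed at 0 in the 4 treated libraries. Pzp (−5.04), Fcamr (−3.82), the thiazide-sensitive transporter Slc12a3 (375 ± 83.7 to 36.4 ± 21.7), Pvalb (−3.53) and Cyp2d12 (−3.32) completed the 10 named. Globin levels also depend on the blood left in the tissue, and the labels do not say how the kidneys were cleared. In each of these genes no treated library overlapped an untreated one.

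In all, limma called 5224 of 15193 genes, 3392 that rose and 1832 that fell, and 1338 of them changed at least 2-fold. The share that rose, 64.9%, depended on scaling: it was 53.4% with median-of-ratios factors and 49.7% with quantile normalization. The median over all genes tested was 0.102 as reported, 0.00919 with median-of-ratios and −0.0146 with quantile normalization, so falls smaller than that shift depend on the scaling. Globin copies share sequence (Hba-a1 with Hba-a2, Hbb-bs with Hbb-bt), as do Cyp4a14 with Cyp4a10. Fgg, Spp1 and Fcamr overlap the gene models Gm30097, Gm42793 and Gm15848. The division of reads among these genes is uncertain.

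Of the 30 tubular injury genes in WT, 29 rose, 0 fell and 1 was not called, and 29 rose and 0 fell when adjusted over the list alone (camera adjusted p = 9.32e-16, adjusted p = 0.180 with an estimated correlation). The urokinase receptor Plaur rose from 4.32 to 44.4 ± 16.0, and the lectin Lgals3 from 23.4 to 219 ± 65.8. Among 30 targets of p53, the transcription factor that answers DNA damage, 25 rose, 1 fell and 4 were not called, and 25 rose and 1 fell when adjusted over the list alone (camera adjusted p = 6.27e-08, adjusted p = 0.339 with an estimated correlation). Examples are the proapoptotic Bax (26.2 ± 2.27 to 98.0 ± 10.2) and Btg2 (3.10 ± 0.40). Of 32 proximal tubule transporters, 2 rose, 17 fell and 13 were not called, and 2 rose and 19 fell when adjusted over the list alone (camera adjusted p = 8.38e-09, adjusted p = 0.115 with an estimated correlation). Slc22a30 fell from 104 ± 11.8 to 17.5 ± 5.34, and the monocarboxylate carrier Slc5a8 from 81.5 to 18 ± 4.44. Of 29 enzymes of proximal tubule metabolism, 2 rose, 20 fell and 7 were not called, and 2 rose and 20 fell when adjusted over the list alone (camera adjusted p = 5.36e-09, adjusted p = 0.205 with an estimated correlation). They include Gatm, an enzyme of creatine synthesis (556 to 85.1 ± 31.3). Thick ascending limb and distal tubule genes also fell: of 20, 2 rose, 13 fell and 5 were not called, and 2 rose and 13 fell when adjusted over the list alone (camera adjusted p = 1.93e-07, adjusted p = 0.180 with an estimated correlation). Kl, which encodes the FGF23 co-receptor klotho, went from 165 ± 5.14 to 41.7 ± 6.64, and Egf from 572 to 133 ± 51.6.

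The list of acyl-CoA synthetases, which holds Acss and Acsf genes beside the Acsm family, was lower in WT after cisplatin: of 9, 0 rose, 8 fell and 1 was not called, and 0 rose and 8 fell when adjusted over the list alone (camera adjusted p = 2.64e-07, adjusted p = 0.115 with an estimated correlation). Acsm2 went from 4456 ± 95.3 (SD, n = 3) to 531 ± 140.2 (SD, n = 4), and Acsm5 from 84.7 to 14.8 ± 2.38. Fatty acid oxidation was not called: of 36 genes, 7 rose, 7 fell and 22 were not called, and 7 rose and 8 fell when adjusted over the list alone (camera adjusted p = 0.467). Its mean of 0.30 and median of 0.05 were positive while camera's direction against the other genes was down. The omega-hydroxylase Cyp4a10 rose (2.29 ± 0.53) and the dehydrogenase Hadh fell (−0.73 ± 0.14). Of 32 genes of the tricarboxylic acid cycle and respiratory chain, 0 rose, 14 fell and 18 were not called, and 0 rose and 15 fell when adjusted over the list alone (camera adjusted p = 1.38e-07, adjusted p = 0.368 with an estimated correlation). In WT cisplatin replicate 1 the score of this list (8.24) lay within the 8.23 to 8.32 of WT untreated, against 7.79 to 8.01 in replicates 2 to 4. The complex I subunit Ndufs1 fell from 231 to 132. Of 13 mitochondrially encoded genes, 0 rose, 3 fell and 10 were not called, and 0 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.00113, adjusted p = 0.339 with an estimated correlation). These were mt-Nd4l (−1.78), mt-Nd5 (−0.65) and mt-Cytb (−0.74), and mt-Nd5 and mt-Cytb lost their call without single libraries.

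Of 29 ferroptosis suppressors in WT, 16 rose, 3 fell and 10 were not called, and 17 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.0107, adjusted p = 0.205 with an estimated correlation). Gch1, which encodes the first enzyme of tetrahydrobiopterin synthesis, rose from 0.542 ± 0.0958 (SD, n = 3) to 3.51 ± 0.466 (SD, n = 4), the heat shock protein Hspb1 from 13.5 to 174 ± 137, and Nfe2l2, the gene of NRF2, from 45.0 to 107 ± 19. Ferroptosis promoters and markers were not called as a list: of 26, 8 rose, 5 fell and 13 were not called, and 9 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.926, direction down, with a mean of 0.21). Acsl4, which loads polyunsaturated fatty acids onto CoA, rose from 10.46 to 39.4 ± 12.2, and the heme oxygenase Hmox1 from 22.3 to 162 ± 103, while the desaturase Fads2 fell from 89.5 to 47.9 ± 3.62. Of 27 NRF2 targets, 21 rose, 1 fell and 5 were not called, and 23 rose and 1 fell when adjusted over the list alone (camera adjusted p = 3.18e-08, adjusted p = 0.271 with an estimated correlation). Pgd, of the pentose phosphate pathway, was at 1.88 ± 0.20 and the glutathione transferase Mgst1 at 2.08 ± 0.23. Of 26 antioxidant enzymes, 6 rose, 1 fell and 19 were not called, and 6 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.984, direction down, with a mean of 0.15).

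Of 28 inflammatory cytokines and NF-kB targets in WT, 25 rose, 1 fell and 2 were not called, and 26 rose and 2 fell when adjusted over the list alone (camera adjusted p = 5.56e-10, adjusted p = 0.271 with an estimated correlation). The endotoxin co-receptor Cd14 rose from 3.34 ± 0.236 (SD, n = 3) to 30.0 ± 9.40 (SD, n = 4), and Saa1, an acute phase protein, was listed at 0 in the untreated libraries and at 3.5 ± 0.771 after cisplatin. Of 23 necroptosis and pyroptosis genes, 10 rose, 0 fell and 13 were not called, and 11 rose and 0 fell when adjusted over the list alone (camera adjusted p = 0.00332, adjusted p = 0.480 with an estimated correlation). They include the necroptosis executor Mlkl (0.959 to 6.35 ± 2.86) and the receptor Tnfrsf1a (70.1 to 224 ± 29.9). Of 25 genes of endoplasmic reticulum stress and the integrated stress response, 22 rose, 1 fell and 2 were not called, and 22 rose and 2 fell when adjusted over the list alone (camera adjusted p = 4.38e-07, adjusted p = 0.205 with an estimated correlation). The stress-induced factor Atf3 was at 3.24 ± 0.42. Of 14 immediate-early genes, 13 rose, 0 fell and 1 was not called, and 13 rose and 0 fell when adjusted over the list alone (camera adjusted p = 6.93e-07, adjusted p = 0.205 with an estimated correlation). The AP-1 subunit Fosl1 was at 3.34 ± 0.28. Of 30 interferon-stimulated genes, 16 rose, 1 fell and 13 were not called, and 21 rose and 1 fell when adjusted over the list alone (camera adjusted p = 5.30e-04, adjusted p = 0.636 with an estimated correlation). Of 29 matrix and fibrosis genes, 9 rose, 0 fell and 20 were not called, and 16 rose and 0 fell when adjusted over the list alone (camera adjusted p = 0.00339, adjusted p = 0.693 with an estimated correlation). Of 27 cell cycle genes, 14 rose, 0 fell and 13 were not called, and 18 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.00264, adjusted p = 0.693 with an estimated correlation). WT cisplatin replicate 1 did not share all of these changes. Its matrix score (mean log2(FPKM + 1)) was 3.25, below the 3.28 to 3.55 of WT untreated, against 4.38 to 4.92 in replicates 2 to 4, and its cell cycle score of 1.80 lay within the 1.70 to 1.82 of WT untreated, against 2.09 to 3.42.

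Markers of other cells moved unevenly in WT. Of 18 macrophage markers, 8 rose, 0 fell and 10 were not called, and 9 rose and 0 fell when adjusted over the list alone (camera adjusted p = 0.00448, adjusted p = 0.636 with an estimated correlation). The macrophage score of WT cisplatin replicate 1 was 2.72, at the upper end of the 2.47 to 2.72 of WT untreated, against 3.26 to 4.37 in replicates 2 to 4. The lysosomal marker Cd68 rose from 3.65 ± 0.944 (SD, n = 3) to 19.9 ± 10.7 (SD, n = 4). Of 12 lymphocyte markers, 0 rose, 2 fell and 10 were not called, and 0 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.0205, adjusted p = 0.576 with an estimated correlation). The B cell gene Cd79a was at −0.91 ± 0.22. All 7 red blood cell genes measured fell (0 not called, 0 rose and 7 fell when adjusted over the list alone) (camera adjusted p = 1.71e-06, adjusted p = 0.205 with an estimated correlation). Endothelial (15 measured, 1 rose, 1 fell and 13 were not called), podocyte (15, 0 rose, 1 fell and 14 were not called), collecting duct (19, 2 rose, 3 fell and 14 were not called) and fibroblast markers (13, 2 rose, 0 fell and 11 were not called) were not called as lists (camera adjusted p = 0.309, 0.367, 0.433 and 0.924). Among the 8 cisplatin libraries, WT replicate 1 and cKO replicate 1 stood low in 3 of these lists. Their endothelial scores (mean log2(FPKM + 1)) were 3.33 and 3.54 against 4.19 to 4.40 in the other 6, their podocyte scores 2.39 and 2.72 against 3.51 to 3.92, and their fibroblast scores 2.36 and 2.65 against 3.07 to 3.97. Without WT replicate 1, left out after its scores were seen, the WT changes of these scores went from −0.213 to 0.0380 (endothelial), from −0.113 to 0.233 (podocyte) and from 0.244 to 0.589 (fibroblast), so their direction or size depended on 1 library. The collecting duct list had a mean of −0.10 and a median of 0.05. Nor were adipose genes (9, 0 rose, 0 fell and 9 were not called), Wnt and epithelial differentiation genes (18, 4 rose, 4 fell and 10 were not called) or RIP kinases (7, 1 rose, 1 fell and 5 were not called), each at a camera adjusted p of 0.926. Adjusted over the list alone, 0 endothelial genes and 2 RIP kinases rose. Of male-biased kidney genes (14 measured), 1 rose, 10 fell and 3 were not called, and 1 rose and 10 fell when adjusted over the list alone (camera adjusted p = 4.00e-07, adjusted p = 0.180 with an estimated correlation). Of 11 female-biased genes, 3 rose, 3 fell and 5 were not called (camera adjusted p = 0.433). The female-biased and Wnt lists had positive means (0.13 and 0.20) while camera's direction was down. Neutrophil markers (4 measured, 1 rose, 0 fell and 3 were not called), adrenal genes (4, 1 rose, 1 fell and 2 were not called), sex chromosome genes (4, 0 rose, 0 fell and 4 were not called) and skeletal muscle genes (1, 0 rose, 0 fell and 1 was not called) were too few to test as lists. Of the 32 lists tested, 21 were called by camera, 18 by fry and 0 with an estimated correlation.

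**Figure D2:**
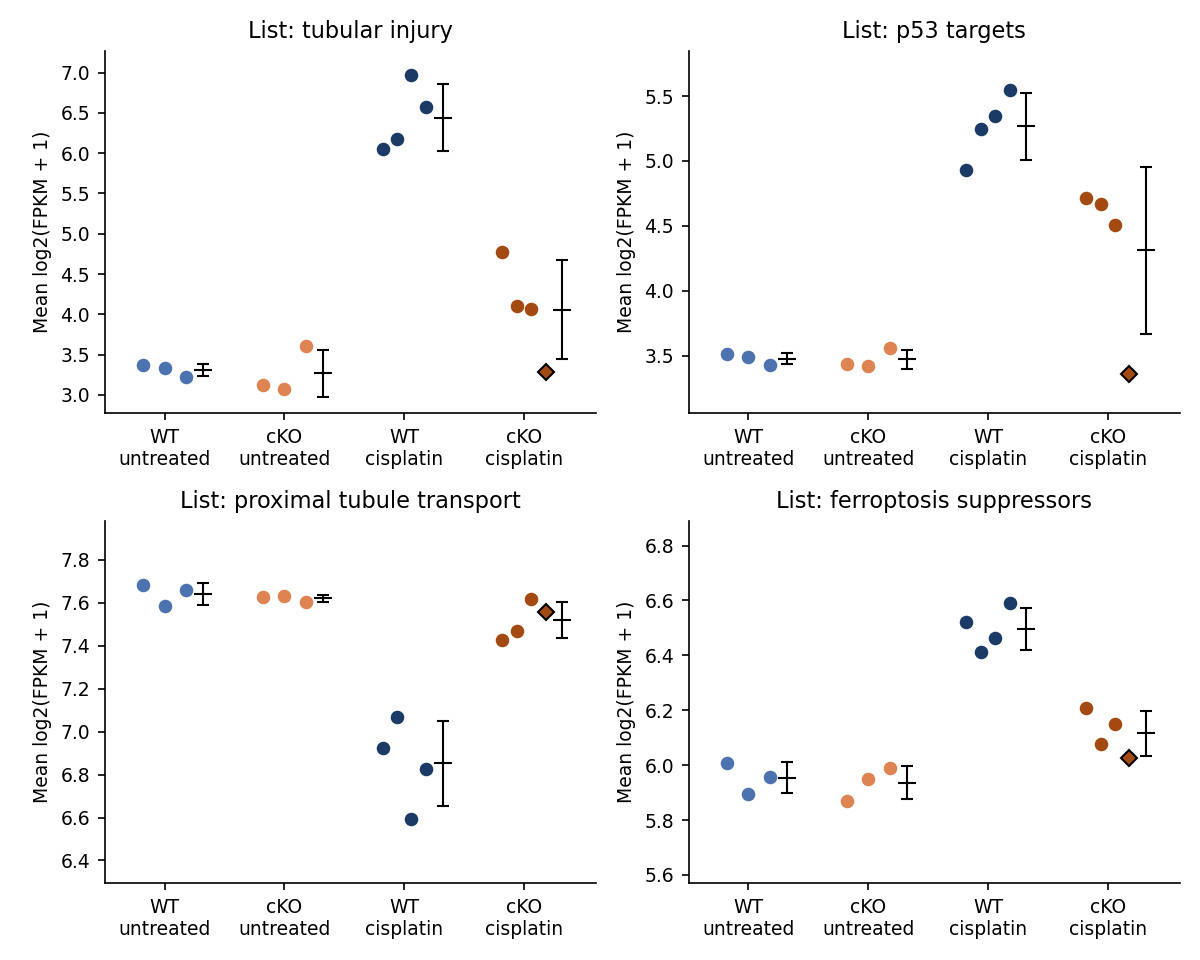
Mean log2(FPKM + 1) over 4 of the gene lists in each kidney library, with the mean and SD of each group in black and the library labelled cKO cisplatin replicate 4 as a black-edged diamond (the axes do not start at 0). The tubular injury score was 3.31 ± 0.0722 (SD, n = 3) in WT untreated, 6.44 ± 0.417 (SD, n = 4) in WT cisplatin and 4.06 ± 0.610 (SD, n = 4) in cKO cisplatin kidneys.

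In cKO kidneys cisplatin changed few genes by the same test. Limma called 3 of 15193, all lower after the drug. The sorting nexin Snx31 fell from 40.3 ± 10.7 (SD, n = 3) to 10.3 ± 3.07 (SD, n = 4), −1.87 ± 0.24 (adjusted p = 0.0209). Ccdc150 fell from 1.86 ± 0.321 to 0.367 ± 0.212 (−1.07 ± 0.14, adjusted p = 0.0209), and the lipid kinase Pi4ka from 135 ± 5.97 to 83.1 ± 5.60 (−0.70 ± 0.10, adjusted p = 0.0271). Pi4ka overlaps Snap29 and Tmem191c. Injury genes had higher means without passing the test: Lcn2 was at 2.94 ± 1.31 and 41.3 ± 48.7, Havcr1 at 5.31 ± 4.93 and 37.1 ± 26.7, and Cdkn1a at 5.06 ± 0.907 and 98.7 ± 69.5. At an unadjusted p under 0.05 there were 1754 genes, against 759.65 that chance gives, and voom called 5. With only the groups compared the count was 0. It was 0 without cKO untreated replicate 1 or without cKO cisplatin replicate 1 or 2, 1 without cKO untreated replicate 2, 2 without WT untreated replicate 2 and 30 without cKO untreated replicate 3. It was 13 without WT cisplatin replicate 1, 5 without WT cisplatin replicate 2 or 4 or cKO cisplatin replicate 3, and 287 without cKO cisplatin replicate 4. Snx31 and Ccdc150 lost their call without cKO untreated replicate 1 or 2 or cKO cisplatin replicate 1 or 2, and Pi4ka lost it also without WT untreated replicate 2 or cKO cisplatin replicate 3.

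The library labelled cKO cisplatin replicate 4 had untreated-like levels. Hbb-bs was 441 FPKM in it, against 0 to 0.533 in the other 7 cisplatin libraries and 305 to 655 in the 6 untreated ones. Cdkn1a was 3.6, against 97.3 to 435 in the other 7 and 3.39 to 6.13 in the untreated ones. Over the 5224 genes called in WT, it moved from the cKO untreated mean by 0.0668 of the mean WT response. The other cKO cisplatin libraries moved by 0.447, 0.371 and 0.310, the WT cisplatin libraries 0.867 to 1.13 and the cKO untreated libraries −0.0899 to 0.106. Genes and scale were taken from WT, so the mean WT share was fixed in advance and the choice favours WT over cKO.

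**Figure D3:**
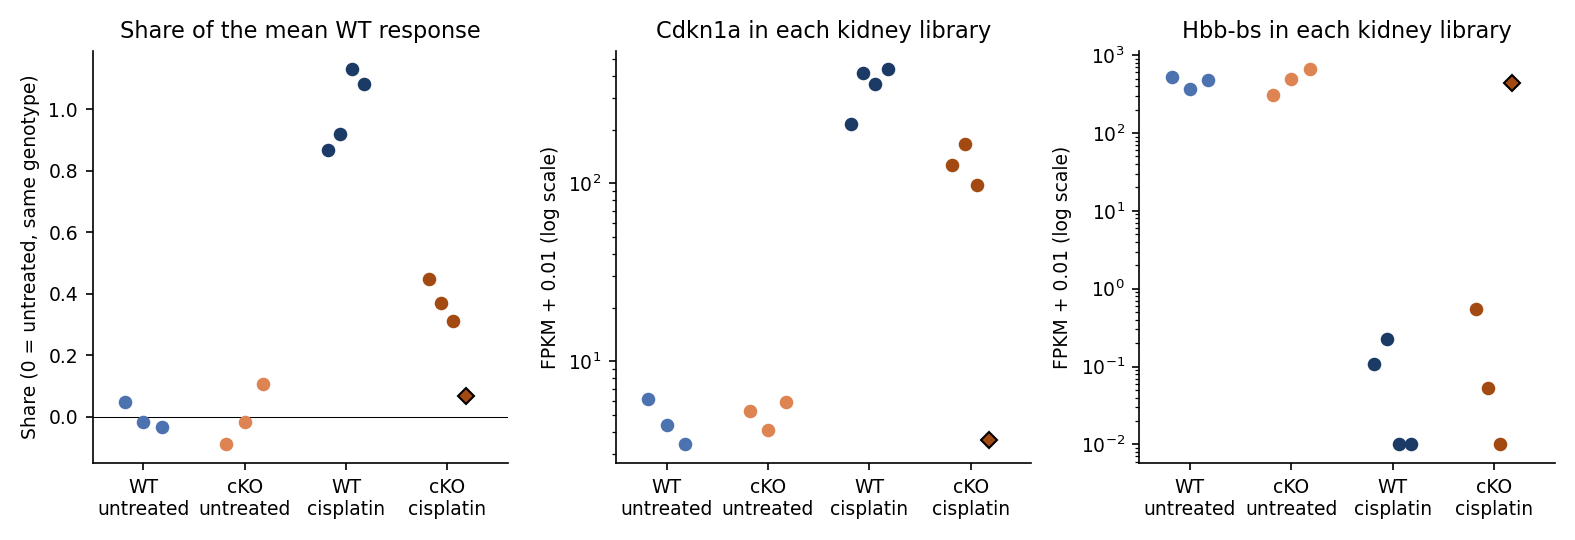
Share of the mean WT cisplatin response over 5224 genes (left, measured from the mean of the untreated libraries of the same genotype), and FPKM + 0.01 of Cdkn1a (middle) and Hbb-bs (right) on log axes, in each kidney library. The black-edged diamond is the library labelled cKO cisplatin replicate 4, at a share of 0.0668, 3.6 FPKM of Cdkn1a and 441 FPKM of Hbb-bs.

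Without that library (n = 3 against 3), a leave-one-out setting singled out after seeing the data, cisplatin raised p53 target and injury genes in cKO. Cdkn1a rose from 5.06 ± 0.907 to 130.4 ± 35 (SD, n = 3), 4.42 ± 0.27 (adjusted p = 2.20e-06). The p53 target Phlda3 rose from 5.2 to 55.1 ± 8.35 (3.21 ± 0.20), Ces2e by 3.28 ± 0.22 and Gdf15 by 3.17 ± 0.32. Lcn2 rose to 54.5 ± 50.03 (adjusted p = 0.00241), C3 to 145 ± 52.6 (3.47 ± 0.37) and Havcr1 to 47.7 ± 20.01 (3.15 ± 0.53). Falls included Hbb-bs (−8.63 ± 0.25), the heme synthesis enzyme Alas2 (−2.87 ± 0.19), Fhit (−3.02 ± 0.18), the mitochondrial protease subunit Immp2l (−2.54 ± 0.16), the organic anion carrier Slco1a1 (−2.12 ± 0.39) and Inmt (−2.09 ± 0.38, to 257 ± 75.6). Limma called 287 genes, 172 that rose and 115 that fell, with 2147 at an unadjusted p under 0.05. Of the 172, 160 also rose in WT, where 38.6 would be shared if the calls were independent, and of the 115, 107 also fell in WT, against 13.8. Both sets of calls come from 1 fit that shares its spread per gene, so they are not independent and these expected numbers may be too low.

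As lists, red blood cell genes were lower after cisplatin in cKO: 0 of 7 fell over all genes and 6 when adjusted over the list alone (camera adjusted p = 7.12e-10, adjusted p = 0.313 with an estimated correlation). Of the 30 p53 targets 0 were called over all genes, and 16 rose and 0 fell when adjusted over the list alone (camera adjusted p = 1.57e-10, adjusted p = 0.438 with an estimated correlation). Of the injury genes 0 were called, and 10 rose and 0 fell when adjusted over the list alone (camera adjusted p = 1.48e-06, adjusted p = 0.565 with an estimated correlation). Of the acyl-CoA synthetases 0 were called, and 0 rose and 5 fell when adjusted over the list alone (camera adjusted p = 2.52e-05, adjusted p = 0.313 with an estimated correlation). Of the immediate-early genes 0 were called, and 4 rose and 0 fell when adjusted over the list alone (camera adjusted p = 2.90e-06, adjusted p = 0.438 with an estimated correlation). NRF2 targets (camera adjusted p = 0.00126, adjusted p = 0.789 with an estimated correlation) and NF-kB targets (camera adjusted p = 7.95e-04, adjusted p = 0.789 with an estimated correlation) were called up with 0 members called. So were endoplasmic reticulum stress genes (camera adjusted p = 9.65e-06, adjusted p = 0.438 with an estimated correlation) and ferroptosis suppressors (camera adjusted p = 0.0280, adjusted p = 0.438 with an estimated correlation). Over the list alone 4, 1, 0 and 0 of these rose. Mitochondrially encoded genes (camera adjusted p = 0.00292, adjusted p = 0.574 with an estimated correlation) and male-biased genes (camera adjusted p = 0.00628, adjusted p = 0.565 with an estimated correlation) were called down with 0 members called. Proximal tubule transport (camera adjusted p = 0.106), proximal tubule metabolism (0.419, direction down, mean 0.07) and ferroptosis promoters (0.735) were not called, but proximal tubule transport was called without replicate 4 (camera adjusted p = 0.0450, adjusted p = 0.648 with an estimated correlation). Camera called 11 of 32 lists, fry 0, and the estimated correlation 0. Without the library labelled cKO cisplatin replicate 4, 19 p53 targets, 10 injury genes, 4 NF-kB targets and 3 immediate-early genes rose over all genes, 6 red blood cell genes, 4 acyl-CoA synthetases and 2 male-biased genes fell, and the red blood cell list held with an estimated correlation (adjusted p = 0.00563).

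Without drug, limma called no gene between cKO and WT kidneys (0 of 15193). With 3 libraries against 3 this does not show that the kidneys were alike. Ripk4 itself was not called, though it was at 3.68 to 4.61 FPKM in the cKO libraries and 7.18 to 8.51 in the WT ones. At an unadjusted p under 0.05 there were 123 genes, fewer than the 759.65 that chance gives, and voom and the fit of only the groups compared also called 0. The model shares its spread per gene with the cisplatin groups, which varied more. For example, the SD of the tubular injury score was 0.0722 and 0.296 in WT and cKO untreated, against 0.417 and 0.610 after cisplatin. Sharing it can make the untreated test too strict, so the low count does not show that the genotypes were alike. Havcr1 was at 5.91 ± 0.996 (SD, n = 3) in WT and 5.31 ± 4.93 (SD, n = 3) in cKO, Lcn2 at 2.52 ± 1.000 and 2.94 ± 1.31, Acsm2 at 4456 ± 95.3 and 4705 ± 706, and Hbb-bs at 458 ± 86.0 and 486 ± 175. The immunoglobulin genes Igkv18-36 (higher in cKO, called without cKO untreated replicate 2) and Igkv3-3 (lower in cKO, called without cKO cisplatin replicate 1) each made a count of 1, and were chosen after their values were seen. Camera called 6 lists, in which 0 members were called. Fatty acid oxidation (0.13) (camera adjusted p = 1.19e-04, adjusted p = 0.953 with an estimated correlation) and the tricarboxylic acid cycle with the respiratory chain (0.05) (camera adjusted p = 0.00365, adjusted p = 0.953 with an estimated correlation) were higher in cKO. Interferon-stimulated genes (−0.17) (camera adjusted p = 0.00468, adjusted p = 0.953 with an estimated correlation) and macrophage markers (−0.20) (camera adjusted p = 0.0368, adjusted p = 0.953 with an estimated correlation) were lower. So were lymphocyte markers (−0.20) (camera adjusted p = 0.00468, adjusted p = 0.953 with an estimated correlation) and immediate-early genes (−0.24) (camera adjusted p = 0.00935, adjusted p = 0.953 with an estimated correlation). Fry called 0 lists. The number of lists was 1 without WT untreated replicate 1, 0 without cKO untreated replicate 1 and 2 without cKO untreated replicate 2. Macrophage markers were not called without cKO cisplatin replicate 4 (camera adjusted p = 0.102).

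After cisplatin, injury genes were far lower and tubule genes higher in cKO than in WT kidneys. Krt20 was 101 ± 39.7 (SD, n = 4) in WT and 3.16 ± 3.17 (SD, n = 4) in cKO, −4.89 ± 0.47 (adjusted p = 8.52e-05). Havcr1 was 739.6 ± 403 against 37.1 ± 26.7 (−4.53 ± 0.65) and Lcn2 388 ± 101 against 41.3 ± 48.7 (−4.16 ± 0.80). The next largest differences of this sign were C3 (−3.37), the cornified envelope gene Sprr2g (−3.37), Cbr3 (−3.21), Fgg (−3.13), the protease inhibitor Timp1 (−3.09), Fosl1 (−3.07) and the TWEAK receptor Tnfrsf12a (−3.03). Inmt was higher in cKO, 494 ± 477 against 16.4 ± 11 (4.60 ± 0.50), as were Hpd (3.07), Slc12a3 (229.6 ± 66.7 against 36.4 ± 21.7), the carbonic anhydrase Car14 (2.73), Dnase1 (2.73), Pvalb (2.72), Cyp2d12 (2.69), Pzp (2.67), Ces1e (2.51) and Slc22a28 (2.41). In each of these genes the 4 cKO libraries lay wholly on 1 side of the 4 WT libraries. Hpd, Car14 and Dnase1 overlap other kept genes (Psmd9, Aph1a, and Trap1 with Gm15879).

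Limma called 4088 of 15193 genes, 1333 higher and 2755 lower in cKO, and 852 differed at least 2-fold. The share that was higher, 32.6%, was 46.7% with median-of-ratios factors and 49.7% with quantile normalization. The median over all genes tested was −0.106 as reported, −0.000853 with median-of-ratios and 0.0176 with quantile normalization. Without the library labelled cKO cisplatin replicate 4, 2889 genes were called, 2804 of them also with all libraries, and Krt20 was at −4.37, Havcr1 at −3.82 and Inmt at 4.04. Without WT cisplatin replicate 1, which stood low in endothelial, podocyte and fibroblast markers, the count was 6201.

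Of 30 tubular injury genes, 0 were higher, 29 lower and 1 not called in cKO after cisplatin, with 29 lower when adjusted over the list alone (camera adjusted p = 1.37e-16, adjusted p = 0.134 with an estimated correlation). Plaur was 44.4 ± 16.0 (SD, n = 4) in WT and 7.49 ± 2.11 (SD, n = 4) in cKO. Of p53 targets, 1 was higher, 19 lower and 10 not called, with 2 higher and 22 lower when adjusted over the list alone (camera adjusted p = 1.36e-04, adjusted p = 0.479 with an estimated correlation). Perp, a desmosomal protein induced by p53, was at −0.78 ± 0.10. Of proximal tubule transporters, 16 were higher, 2 lower and 14 not called, with 21 and 2 when adjusted over the list alone (camera adjusted p = 5.70e-11, adjusted p = 0.101 with an estimated correlation). Slc34a3, a sodium phosphate cotransporter, was 65.6 ± 25.6 in cKO and 22.1 ± 7.21 in WT. Of enzymes of proximal tubule metabolism, 20 were higher, 0 lower and 9 not called, with 22 and 1 when adjusted over the list alone (camera adjusted p = 3.67e-13, adjusted p = 0.108 with an estimated correlation). The urea cycle enzyme Ass1 was 3462 ± 319 in cKO and 1232 ± 359.9 in WT. Of thick ascending limb and distal tubule genes, 13 were higher, 0 lower and 7 not called, with 14 and 1 when adjusted over the list alone (camera adjusted p = 3.23e-09, adjusted p = 0.108 with an estimated correlation). Egf was 456 ± 67.6 in cKO and 133 ± 51.6 in WT. Of collecting duct markers, 5 were higher, 0 lower and 14 not called (camera adjusted p = 0.0135, adjusted p = 0.378 with an estimated correlation). The receptor gene Insrr was at 1.20 ± 0.17. Red blood cell genes, with 0 of 7 called, had a mean of 1.24 (camera adjusted p = 0.0111, adjusted p = 0.479 with an estimated correlation). Of male-biased genes, 10 were higher, 1 lower and 3 not called (camera adjusted p = 3.66e-08, adjusted p = 0.108 with an estimated correlation). Of female-biased genes these numbers were 3, 1 and 7 (camera adjusted p = 0.0167, adjusted p = 0.275 with an estimated correlation). Without the library labelled cKO cisplatin replicate 4, the red blood cell list had a mean of 0.176 and was not called (camera adjusted p = 0.105), nor were female-biased genes (camera adjusted p = 0.0516), and 3 collecting duct markers were higher.

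Acyl-CoA synthetases were higher in cKO after cisplatin: 6 of 9 were higher, 0 lower and 3 not called, with 7 and 0 when adjusted over the list alone (camera adjusted p = 3.62e-07, adjusted p = 0.101 with an estimated correlation). Acsm2 was 2457 ± 639 (SD, n = 4) in cKO and 531 ± 140.2 (SD, n = 4) in WT, and Acsm5 57.6 ± 19.1 and 14.8 ± 2.38. Of tricarboxylic acid cycle and respiratory chain genes, 18 were higher, 0 lower and 14 not called, with 21 and 0 when adjusted over the list alone (camera adjusted p = 7.40e-12, adjusted p = 0.275 with an estimated correlation). For fatty acid oxidation 7 were higher, 1 lower and 28 not called, and camera called the list up (camera adjusted p = 0.0135, adjusted p = 0.666 with an estimated correlation). Its median was 0.10 and its mean −0.01, which turned positive with median-of-ratios (0.11) and quantile scaling (0.05). Of ferroptosis suppressors, 2 were higher, 15 lower and 12 not called, with 3 and 16 when adjusted over the list alone, and the list missed the threshold (camera adjusted p = 0.0680). Gch1 was 0.743 ± 0.292 against 3.51 ± 0.466 and Hspb1 22.6 ± 6.91 against 174 ± 137. The enzyme Cbs of cysteine synthesis was higher at 193 ± 21.9 against 99.6 ± 36.1. Of ferroptosis promoters and markers, 5 were higher, 8 lower and 13 not called, with 5 and 8 when adjusted over the list alone (camera adjusted p = 0.875). Acsl4 was 14.3 ± 3.65 against 39.4 ± 12.2 and Hmox1 30.7 ± 14.1 against 162 ± 103, while Fads2 was higher at 74.1 ± 8.87 against 47.9 ± 3.62. Of NRF2 targets, 0 were higher, 20 lower and 7 not called, with 1 and 24 when adjusted over the list alone (camera adjusted p = 2.70e-08, adjusted p = 0.275 with an estimated correlation). The sulfiredoxin gene Srxn1 was 75.3 ± 23.9 against 384 ± 227. Antioxidant enzymes had 1 higher, 5 lower and 20 not called (camera adjusted p = 0.357, direction up, with a mean of −0.03). With that library left out (labelled cKO cisplatin replicate 4), 10 genes of the tricarboxylic acid cycle and respiratory chain and 2 ferroptosis promoters were higher. Ferroptosis suppressors were then called as a list (camera adjusted p = 0.0453), with 1 higher and 10 lower, but not with an estimated correlation (adjusted p = 0.278).

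Of inflammatory cytokines and NF-kB targets, 0 were higher, 26 lower and 2 not called in cKO after cisplatin, with 1 and 26 when adjusted over the list alone (camera adjusted p = 3.59e-12, adjusted p = 0.275 with an estimated correlation). Csf1, a growth factor of macrophages, was 8.29 ± 2.10 (SD, n = 4) against 59.7 ± 33.7 (SD, n = 4). Of necroptosis and pyroptosis genes 12 were lower and 11 not called (camera adjusted p = 8.24e-05, adjusted p = 0.297 with an estimated correlation). Mlkl was 1.34 ± 0.191 against 6.35 ± 2.86. Of interferon-stimulated genes 23 were lower and 7 not called (camera adjusted p = 2.56e-07, adjusted p = 0.395 with an estimated correlation). Of matrix genes 13 were lower and 16 not called (camera adjusted p = 3.41e-04, adjusted p = 0.525 with an estimated correlation), and of cell cycle genes 18 and 9 (camera adjusted p = 3.45e-05, adjusted p = 0.484 with an estimated correlation). Of endoplasmic reticulum stress genes 1 was higher, 18 lower and 6 not called (camera adjusted p = 3.79e-06, adjusted p = 0.275 with an estimated correlation). Of immediate-early genes 11 were lower and 3 not called (camera adjusted p = 5.95e-06, adjusted p = 0.275 with an estimated correlation). Of macrophage markers 11 were lower and 7 not called (camera adjusted p = 1.33e-04, adjusted p = 0.464 with an estimated correlation). Cd68 was 3.97 ± 1.24 against 19.9 ± 10.7. The 4 neutrophil markers measured were lower, too few to test as a list, and 0 were called without the library labelled cKO cisplatin replicate 4. Lymphocyte (0 of 12 called) and endothelial markers (0 of 15 called) were not called as lists (camera adjusted p = 0.656 and 0.466). In all, camera called 22 of 32 lists, fry 20 and the estimated correlation 0.

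The difference of the responses asks whether cisplatin acted differently in cKO. Krt20 went from 0.218 to 101 ± 39.7 in WT (SD, n = 4) and from 0.350 to 3.16 ± 3.17 in cKO (SD, n = 4), a difference of −5.02 ± 0.71 (adjusted p = 0.0103). Sprr2g (−3.10 ± 0.43), the aldo-keto reductase Akr1b8 (−3.18 ± 0.53), Smpdl3b (−2.91 ± 0.47), Fosl1 (−2.90 ± 0.40) and the proto-oncogene Myc (−2.36 ± 0.41) also had called negative differences. Inmt had a called positive difference, 4.52 ± 0.76 (adjusted p = 0.0129), with means from 1087 ± 277 to 494 ± 477 in cKO against 1009.8 ± 68.6 to 16.4 ± 11 in WT. So did Acsm2 (2.15 ± 0.34), Acsm5 (1.80 ± 0.28), Slc22a30 (1.89 ± 0.32), Tmem52b (2.09 ± 0.34) and Kl (1.38 ± 0.17). Gch1 (−1.40 ± 0.21) and the translation repressor Eif4ebp1 (−1.69 ± 0.23) had called negative differences. Each gene named so far in this comparison kept its call when any single library was left out. Other large differences were called with all libraries but lost their call without 1 or more single libraries: Havcr1 (−4.14, adjusted p up to 0.101), Spp1 (−2.997, up to 0.0838), Slc12a3 (3.07, up to 0.062), Hmox1 (−2.34, up to 0.104) and Acsl4 (−1.35, up to 0.113). Without the library labelled cKO cisplatin replicate 4, Cdkn1a was at −1.55 (adjusted p = 0.05125) and not called.

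Limma called 617 of 15193 genes, 214 with a positive and 403 with a negative difference, and 363 differed at least 2-fold. The positive share was 34.7%, and 44.8% with quantile normalization. It was 64.0% of the 100 genes called without the 3 libraries whose titles carry a higher number series. These are WT cisplatin replicate 2 and cKO cisplatin replicates 2 and 3, and without them cKO cisplatin holds only replicate 1 and the untreated-like replicate 4. The count was 229, 84 and 91 without WT untreated replicate 1, 2 or 3, and 319, 185 and 98 without cKO untreated replicate 1, 2 or 3. It was 2245, 400 and 324 without WT cisplatin replicate 1, 3 or 4, and 263 and 332 without cKO cisplatin replicate 3 or 4. Over 4697 genes called for the mean effect of both genotypes, the mean signed response was 0.875 in WT and 0.320 in cKO, a difference of −0.555 (exact permutation p = 0.0186, two-sided). It was −0.570 over the 3034 genes that rose and −0.528 over the 1663 that fell. Without the library labelled cKO cisplatin replicate 4 it was −0.485 (exact permutation p = 0.020). It missed the threshold without the 3 libraries of the higher number series (−0.591, exact permutation p = 0.055) and without the 3 libraries with the highest FPKM totals (−0.484, exact permutation p = 0.070).

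**Figure D4:**
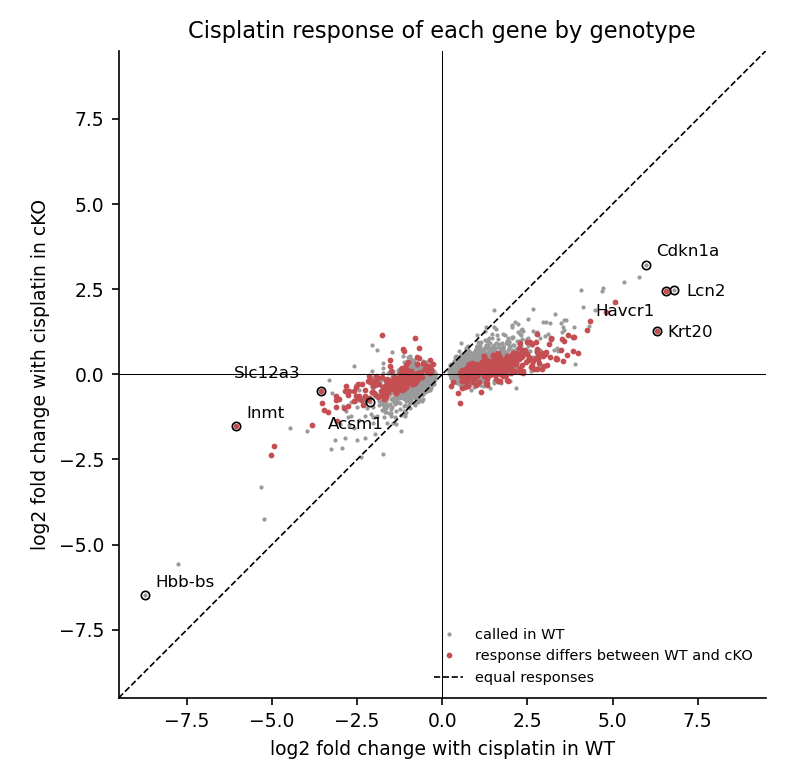
Log2 fold change with cisplatin in WT (horizontal) against that in cKO (vertical) for genes called in WT (grey) and genes whose response differed between genotypes (red), with equal responses on the dashed line and 8 genes labelled. Krt20, at 6.31 in WT, and Inmt, at −6.04 in WT, lie far from the dashed line, towards 0 on the cKO axis.

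As lists, the injury genes responded less in cKO: 18 of 30 had a called negative difference, 0 a positive one and 12 were not called, with 28 negative when adjusted over the list alone (camera adjusted p = 4.22e-19, adjusted p = 0.106 with an estimated correlation). The injury score rose by 3.13 in WT (exact permutation p = 0.0286) and stood 0.79 higher in cKO without passing (exact permutation p = 0.0857). The difference of −2.34 had an exact permutation p of 0.0171. For p53 targets 3 were negative and 27 not called, with 13 negative when adjusted over the list alone (camera adjusted p = 5.43e-05, adjusted p = 0.509 with an estimated correlation). Proximal tubule transport (4 positive, 28 not called) (camera adjusted p = 7.40e-10, adjusted p = 0.0909 with an estimated correlation) and proximal tubule metabolism (6 and 23) (camera adjusted p = 2.69e-12, adjusted p = 0.106 with an estimated correlation) had positive differences. So did thick ascending limb with distal tubule (6 and 14) (camera adjusted p = 1.78e-10, adjusted p = 0.0909 with an estimated correlation), acyl-CoA synthetases (3 and 6) (camera adjusted p = 6.07e-07, adjusted p = 0.0909 with an estimated correlation) and male-biased genes (4 and 10) (camera adjusted p = 1.23e-08, adjusted p = 0.0909 with an estimated correlation). Over the list alone these were positive for 10, 15, 9, 5 and 8 genes. NF-kB targets (7 negative, 21 not called) (camera adjusted p = 3.85e-12, adjusted p = 0.308 with an estimated correlation) and NRF2 targets (8 and 19) (camera adjusted p = 1.67e-08, adjusted p = 0.308 with an estimated correlation) had negative differences. So did immediate-early genes (3 and 11) (camera adjusted p = 4.89e-05, adjusted p = 0.308 with an estimated correlation), endoplasmic reticulum stress genes (2 and 23) (camera adjusted p = 2.59e-05, adjusted p = 0.308 with an estimated correlation) and ferroptosis suppressors (3 and 26) (camera adjusted p = 0.0446, adjusted p = 0.308 with an estimated correlation). The suppressor score differed by −0.36 (exact permutation p = 0.020). Ferroptosis promoters (1 positive, 2 negative) and fatty acid oxidation (0 called) were not called as lists (camera adjusted p = 0.946 and 0.330). Without the library labelled cKO cisplatin replicate 4, negative differences were called for 16 injury genes, 2 p53 targets, 2 ferroptosis suppressors, 3 NRF2 targets, 1 immediate-early gene and 1 endoplasmic reticulum stress gene, and for 7 NF-kB targets, as with all libraries. Positive ones were called for 3 genes of proximal tubule metabolism, for 4 acyl-CoA synthetases, 1 more than with all libraries, and for as many genes as before in the lists of proximal tubule transport (4), thick ascending limb with distal tubule (6) and male-biased genes (4). Of ferroptosis promoters 0 were called. Camera called 21 of 32 lists, 9 up and 12 down, not all of them described here, fry called 12 and the estimated correlation 0. Of 30 list scores compared over 6 lists and 5 comparisons, 13 had an exact permutation p under 0.05.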

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

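Single libraries far from the other 3 of their group were looked for in 96 values of the cisplatin groups, by comparing the gap to the nearest library with the range of the group. Chance marks about 1 in 20 groups, and 9 of 96 were marked. The library labelled cKO cisplatin replicate 4 was marked in 6 of them. Its gap took up 0.851 of the group's range for Cdkn1a, 0.930 for Hbb-bs, 0.923 for Hba-a1, 0.946 for Hba-a2, 0.926 for Hbb-bt and 0.849 for the p53 target score. Slc12a3 stood apart in cKO cisplatin replicate 1 (0.837), and Cyp2d12 in WT cisplatin replicate 4 (0.888). The FPKM total of WT cisplatin replicate 1 was marked at 0.839 (769580.0 against 705412 in the nearest library).

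Other results were marked because the cisplatin responses of the genotypes differed by the test of the difference: 617 genes, and the mean signed response, by −0.555 (exact permutation p = 0.0186). The largest positive differences, cKO minus WT, were Inmt 4.52, Slc12a3 3.07, the immunoglobulin gene Ighv1-12 2.90, Pvalb 2.69, Pzp 2.67, Ces1e 2.50, Dnase1 2.49, Car14 2.36, Slc7a13 2.36 and Slc22a28 2.33. The largest negative ones were Krt20 −5.02, Havcr1 −4.14, Serpina10 −3.37, Akr1b8 −3.18, Cbr3 −3.14, Sprr2g −3.10, Spp1 −2.997, Fgg −2.96, Tnfrsf12a −2.94 and Smpdl3b −2.91.

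For the library labelled cKO cisplatin replicate 4, all tests were chosen only after its levels were seen, and its share of the WT response was 0.0668, within the −0.0899 to 0.106 of the cKO untreated libraries, which is consistent with a kidney that received no cisplatin, by a wrong label or an injection that delivered no drug. By genes over 200 kb it cannot be told apart, since their fall of −0.0709 lay beyond the −0.0521 to −0.00606 of the cKO untreated libraries but short of the −0.0891 to −0.256 of the other 3 cKO cisplatin libraries. An exchange with 1 of the 6 untreated libraries is excluded, since the highest Cdkn1a among these was 6.13 FPKM, while the other 7 cisplatin libraries held at least 97.3. Hbb-bs at 441 FPKM in the library itself, against at most 0.533 in the other 7, does not decide whether the animal was exposed, since globin may reflect blood left in the tissue and the labels do not say how kidneys were cleared. A wrong label, a failed injection and an exposed kidney that did not respond stay open.

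For the smaller response in cKO, 3 tests were chosen only after the result was seen. The test on long genes was devised after the globin test left exposure open and after long genes (Fhit, Immp2l) were seen among the falls, but before its own values were seen. The library labelled cKO cisplatin replicate 4 alone is excluded as the whole cause, since the difference was −0.485 without it (exact permutation p = 0.020). With the FPKM total as a covariate 1667 genes were called, so differences remained after that adjustment. A count of calls does not measure how much of the smaller response the totals carry, so a part from FPKM totals stays open. Lower exposure to the drug in cKO animals cannot be told apart from a genotype effect: globins reached 0.822 FPKM in cKO replicates 1 to 3 and 0.494 in WT but may reflect blood left in the tissue, and the mean of long genes (−0.147) joins −0.256 in replicate 1, within the WT range of −0.338 to −0.176, with −0.0891 and −0.0967 in replicates 2 and 3, above it and close to the −0.0709 of replicate 4. The groups were set by genotype, but a measure of platinum in the kidney would be needed to tell its effect from lower exposure.

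For Ripk4 at the WT level in the library labelled cKO cisplatin replicate 3 (9.09 FPKM), both tests were chosen only after the result was seen. A WT kidney under that label cannot be told apart: its share of the WT response was 0.310 against 0.867 to 1.13, but a WT kidney less exposed to the drug could also have a low share, and its Ripk4 lay within the WT range of 7.61 to 13.3. More collecting duct in that piece is excluded, since its collecting duct score differed by −0.0110 from the other 3 cKO cisplatin libraries, whose SD was 0.114, while log2 Ripk4 was higher by 0.804. Incomplete deletion stays open and was not tested.

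Each comparison was also run on splits of its libraries that mix the groups, a test set before its results were seen. For cisplatin in WT, 1 of 35 splits (the real one, with 5224 genes, the highest other 4685) gave as many genes, but 14 of 35 gave as many lists (21, the highest other 24). For cisplatin in cKO, 2 of 35 gave as many genes (3, the highest other 296, from the split that joins replicate 4 with the untreated libraries), and 18 of 35 as many lists (11 against 21). For cKO against WT after cisplatin, 2 of 35 gave as many genes (4088, the highest other 4141, from exchanging WT cisplatin replicate 1 with cKO cisplatin replicate 2), and 8 of 35 as many lists (22 against 25). That split puts the 3 libraries with the highest FPKM totals on the same side. For the difference of responses, 3 of 100 splits drawn gave as many genes (617 against 969), and 20 of 100 as many lists (21 against 26). Without drug there were only 10 splits, too few to tell: 10 gave as many genes (0) and 2 as many lists. List calls by camera at the preset correlation may therefore arise from chance splits in the other 4 comparisons. The limit set was that fewer than 0.05 of the splits give as many calls. Gene counts met it for cisplatin in WT and for the difference of responses. At 2 of 35 splits they missed it for cisplatin in cKO and for genotype after cisplatin.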

How the results depend on the processing

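Most results kept their direction and their side of the threshold. Of the named genes and list members, 2906 values for cisplatin in WT stayed the same, 16 were weaker and 7 stronger. For cisplatin in cKO 1560 stayed, 22 were weaker and 125 stronger, and for genotype after cisplatin 3122 stayed, 42 were weaker and 29 stronger. For the difference of responses 2356 stayed, 485 were weaker and 126 stronger. A 2-fold limit left 1338 genes for cisplatin in WT, 2 in cKO, 852 for genotype after cisplatin and 363 for the difference of responses, and an adjusted p under 0.1 gave 67 in cKO and 1329 for the difference of responses. For cisplatin in cKO the count was 5 with a pseudocount of 5, median-of-ratios scaling, no mean-variance trend or voom, 12 with no filter, 10 with each library scaled to the same total, 874 with array weights, 0 without the 3 libraries of the higher number series, 410 without the 3 libraries with the highest FPKM totals, 114 with the FPKM total as a covariate and 0 with only the groups compared. For genotype after cisplatin it was 2479 without the higher number series and 2124 with only the groups compared. For the difference of responses it was 255 with no filter, 3429 with array weights, 100 without the higher number series, 1781 without the highest FPKM totals and 1667 with the covariate. Lists called were 0 with an estimated correlation in each of the 5 comparisons, and by fry 0 for cisplatin in cKO, 0 for genotype without drug and 12 for the difference of responses. The cause of these moves was not tested.

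For Ripk4, array weights gave 0.69 for cisplatin in cKO (adjusted p = 0.0495) and −0.45 after cisplatin (0.0965), and leaving out the highest FPKM totals gave −0.54. With only the groups compared it was −0.72 (adjusted p = 0.0806). For Acsm1 in cKO, array weights gave −0.98 and leaving out the highest totals −1.25, and for its difference of responses these gave 1.24 and 0.92. The size of the response was −0.591 without the higher number series (exact permutation p = 0.055) and −0.484 without the highest totals (0.070). Of the 30 list scores 1 passed in each of these settings, and the smallest p rises with fewer libraries.

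Leaving out 1 library at a time gave these lowest and highest values. Genes called were 3827 to 6466 for cisplatin in WT, 0 to 287 in cKO, 0 to 1 for genotype without drug, 2803 to 6201 after cisplatin and 84 to 2245 for the difference of responses. Lists called were 20 to 21, 10 to 14, 0 to 9, 20 to 23 and 18 to 23 in that order, and list scores passing 7 to 13. Ripk4 was 0.17 to 0.41 with cisplatin in WT, 0.19 to 0.56 in cKO, −0.88 to −0.75 without drug, −0.92 to −0.55 after cisplatin and −0.11 to 0.27 for the difference. Acsm1 was −2.22 to −2.05, −1.20 to −0.57, −0.034 to 0.15, 1.00 to 1.62 and 0.93 to 1.55. The size of the response was −0.643 to −0.485 (exact permutation p = 0.010 to 0.0286). Without cKO cisplatin replicates 3 and 4 together, 211 genes were called in cKO, 1350 for genotype after cisplatin and 18 for the difference of responses, Acsm1 in cKO was at −1.30, and 6 list scores passed. The size of the response was then −0.457 (exact permutation p = 0.0433).

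Reversed values were mostly near 0. The p53 targets score, cKO versus WT, untreated, was 0.00624 with a pseudocount of 0.1, 0.0270 with median-of-ratios and 0.0214 with quantile scaling, and −0.0466 to 0.0202 without single libraries. The ferroptosis promoters and markers score, cisplatin versus untreated in cKO, was −0.00126 with a pseudocount of 5, −0.0131 with median-of-ratios, −0.0250 with equal totals, −0.0288 with quantile scaling and −0.0429 without the higher number series, and −0.0180 to 0.0594 without single libraries. The fatty acid oxidation score, cKO versus WT, after cisplatin, was 0.109 with median-of-ratios, 0.0475 with quantile scaling, 0.221 without the higher number series and 0.0853 without cKO cisplatin replicates 3 and 4, and −0.215 to 0.167 without single libraries. The fatty acid oxidation score, difference of the cisplatin responses, cKO minus WT, was 0.0896 without the higher number series and −0.347 to 0.0348 without single libraries. Median-of-ratios gave 0.0157 for the proximal tubule transport score, cKO versus WT, untreated. It gave 0.0185 for the ferroptosis suppressors score, cKO versus WT, untreated, which ran from −0.0467 to 0.0160 without single libraries. The tubular injury score, cKO versus WT, untreated, ran from −0.212 to 0.0548. Without drug and without single libraries, Krt18, cKO versus WT, untreated, ran from −0.042 to 0.61, Sprr1a, cKO versus WT, untreated, from −0.16 to 0.75 and Dhodh, cKO versus WT, untreated, from −0.019 to 0.17. Ripk4 was at −0.18 for the difference of responses without the higher number series, and Alas2, difference of the cisplatin responses, cKO minus WT, was −0.00783 without the highest totals. The cause was not tested.

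No paired analysis was possible because the labels give no pairing. Sex as a covariate was not run, since all libraries read as male. Of count tools, limma voom was run on the recovered reads, and DESeq2, planned only for a table of counts, was not run. With only the groups compared, the difference of responses is the same fit. Depth was 36.7 to 77.0 M reads, and genes below a mean of 0.5 FPKM (34391) were not tested.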

Other observations

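Genes of long genomic span were lower after cisplatin. The median log2 fold change in WT fell with span, from 0.15 for 7754 genes under 20 kb through 0.10 (20 to 50 kb), 0.05 (50 to 100 kb) and 0.01 (100 to 200 kb) to −0.15 for 615 genes over 200 kb. Of these 615, 40 rose and 161 fell in WT, against 2036 and 766 of those under 20 kb. In cKO the medians were 0.08, 0.00, −0.04, −0.06 and −0.12. Fhit, a fragile site gene, and Immp2l were among the falls in cKO without the library labelled replicate 4. Per library, long genes against genes of 20 to 100 kb stood at −0.00198, −0.0120 and 0.0136 in WT untreated and −0.0521, −0.00606 and −0.0319 in cKO untreated. They stood at −0.338, −0.176, −0.271 and −0.231 in WT cisplatin and −0.256, −0.0891, −0.0967 and −0.0709 in cKO cisplatin (replicate 4 last).

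Over the 21 lists called for cisplatin in WT, the cKO cisplatin libraries 1 to 3 kept different shares of the WT change of the list score. Their mean, taken from the WT untreated mean (in brackets from the cKO untreated mean), was highest for lymphocyte markers at 1.34 (0.805), red blood cell genes at 0.962 (0.954), mitochondrially encoded genes at 0.796 (0.765) and p53 targets at 0.645 (0.647). It was lowest for interferon-stimulated genes at −0.188 (0.0217), followed by cell cycle genes at −0.0507 (−0.146), macrophage markers at −0.0444 (0.166), the tricarboxylic acid cycle and respiratory chain at −0.00600 (0.157) and necroptosis and pyroptosis at 0.00327 (0.123). Matrix genes were at 0.0422 (0.113), proximal tubule metabolism at 0.0600 (−0.0197), thick ascending limb with distal tubule at 0.137 (0.0485) and proximal tubule transport at 0.173 (0.145), and the other 8 lists between 0.242 and 0.396. For p53 targets the single libraries were at 0.69, 0.667 and 0.576, against 0.811 to 1.16 in WT. For proximal tubule transport they were at 0.270, 0.217 and 0.032 and for proximal tubule metabolism at 0.204, 0.0452 and −0.0690, so the last mean rests on replicate 1. The WT cisplatin libraries themselves ran from −0.0424 to 1.79 for lymphocyte markers and from 0.356 to 1.76 for mitochondrially encoded genes. They ran from −0.210 to 1.76 for matrix genes and 0.0392 to 2.15 for cell cycle genes, but only from 0.979 to 1.01 for red blood cell genes. Taken from the cKO untreated mean, red blood cell genes were highest and cell cycle genes lowest. The difference between lists was not tested.

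Hypothesis, written before its values were seen: cisplatin crosslinks stall transcription, so long genes lose more transcript than short ones. Genes over 200 kb fell against genes of 20 to 100 kb by 0.254 in WT (exact permutation p = 0.0286, the smallest possible with 3 against 4 libraries), which is consistent with it. Among genes with exons of 2 to 5 kb (381 against 2662) the fall was −0.214 (−0.270 to −0.181 over the 4 libraries). Lengths in that range were not matched, so a part from length stays open. In cKO the fall was 0.0982 (exact permutation p = 0.0571), the genotypes differed after cisplatin by 0.126 (exact permutation p = 0.0857), and the difference of responses was 0.156 (exact permutation p = 0.0271). The largest fall of each genotype was in replicate 1, the 2 libraries that stood low in endothelial, podocyte and fibroblast markers. Fewer of these cells as the whole cause is excluded by a test chosen after the values were seen, since the 3 WT cisplatin libraries with those markers not below the untreated range still fell, by −0.271 to −0.176. A part of the fall from other changes of cell types stays open.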
